A study of Drosophila melanogaster with 12 samples.

How the data were processed

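Heads of Drosophila melanogaster from 3 monogamous and 3 polygamous populations were sequenced, 1 library per population and sex, 12 in all. Per the labels' protocols, RNA was extracted with RNAzol and libraries were made with an Illumina mRNA-Seq kit. Per the submitters' processing notes, the reads were aligned with TopHat2 to genome build BDGP5, counted with HTSeq and handled with DESeq2; versions and parameters are not given in the sources used here. The deposited values are a signal per gene: the authors scaled the reads of each gene by 1 factor per library, as the values show, so that every column sums to nearly the same total, 45916924 to 45943793, and rounded to 2 decimals. Every one of the 11236 genes lies above 0 in all 12 columns, which points to a filter by the authors or before deposit. No column was left unused (0). How many flies went into a library is not stated in the sources used here.

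The deposited scaling left each value a whole multiple of the value of 1 read in its library. Dividing by that value gave whole reads for 100% of values in every library, at a tolerance of 0.1 reads, and recovered totals of 34558521 to 52282995 reads. Because the scaling equalises totals, a few abundant genes that differ between groups shift all others, and rescaled values were tried for that reason. The counting mode for strand is not stated, so reads of overlapping or antisense genes could not be assigned with certainty, and values of near-identical copies, such as the Hsp70 genes, are uncertain. Flybase identifiers were matched to symbols with a reference gene table: 10781 identifiers had a symbol and 455 had none, 10782 had a chromosome, and 1766 of these lay on X. The reference follows a later build than the authors' files, so no coordinates are given.

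The planned test assumed normalised values, which the files hold. Values were transformed to log2(value + 1), genes with a mean of 10 or more over the 12 libraries were kept (10568), and limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 was fitted with 1 mean per group over all 12 libraries, so that the 4 groups shared 1 estimate of spread. Contrasts were monogamous minus polygamous in each sex, male minus female over all populations and within each mating system, and the difference of the sex differences. The mating difference over both sexes was tested on 6 population means. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Positive values mean higher under monogamy or in males. These tests, the gene lists, the rule for named genes and the alternatives were set before the data were examined, except where an alternative is said to have been added.

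Genes were named by a fixed rule: among genes past the threshold whose 2 groups of libraries do not overlap, the 12 with the largest positive and the 12 with the largest negative log2 fold change; where fewer than 10 genes passed, the 10 with the smallest p, said not to pass; up to 4 members with the smallest p of each list; and always Yp1, Yp2, Yp3, roX1, roX2, Sxl, tra, dsx, fru, to, fit and msl-2. Of the gene lists, 33 with 5 or more tested members were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), camera with an estimated correlation, and fry, which asks whether members move one way on balance. They cover fat body, sex determination, dosage compensation, immunity, chemosensation, vision, the clock, neuropeptides and amines, detoxification, cuticle and pheromones, metabolism and hormones, stress, core cell machinery, and markers of other tissues and cell types. The lists for the accessory gland and the salivary gland had 3 tested members each and are given gene by gene. The lists of Y-linked genes and of the mitochondrial genome had 0 genes in the file. Some single-gene results are not reported here. Scores of sex-biased genes were compared by exact two-sided permutation of 3 against 3 populations, whose smallest p is 0.1. X linkage was tested with Fisher's exact test.

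Library numbers are shared between sexes and mating systems. The male and female libraries of 1 number come from the same population by the labels, and their deviations from group means correlated at 0.0908 to 0.474 (mean 0.217), against -0.329 to 0.052 for male and female libraries of different populations in 1 mating system. Deviations from a group mean cancel within the group, so positive values within populations force negative ones between them on average. The ranges are therefore not independent evidence of pairing. Between mating systems, libraries of 1 sex with different numbers reached 0.224, above the lowest value within a population. Because both sexes of a number share a population by the labels, they were treated as paired in an alternative, the replicate block. There populations were the block for the sex comparisons and the interaction, and library numbers were the block for comparisons of mating systems. Numbers across mating systems name different populations, so the latter block does not pair them.

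Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of 50 or more (11236 and 9374 genes), TMM and upper-quartile rescaling, no variance trend, a threshold of 0.10, only the libraries compared, the replicate block, leaving out each population, and sex-biased genes defined by a fold of 2, in polygamous or in monogamous populations. edgeR 4.0.16 (glmQLFit and glmQLFTest) and DESeq2 1.42.0 were run on the recovered reads. For the mating difference over both sexes they used the reads of a population summed over its sexes. Array weights, TMM rescaling for the test of X linkage and all fits without the female library of monogamous population 1 alone were added after the data had been seen. Exon lengths were known for 95.9% of tested genes. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

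The scripts were tested on simulated data: reads drawn for the 10568 tested genes with known changes in 67, 67 and 66 genes of 1.5-fold, 2-fold and 3-fold. For mating males limma recovered 26.9%, 70.1% and 78.8% and called 5 unchanged genes, and for mating females 17.9%, 67.2% and 86.4% with 4 unchanged genes. Over both sexes it recovered 47.8%, 76.1% and 87.9%, for the sexes 56.7%, 86.6% and 95.5%, and for the interaction 6.0%, 43.3% and 72.7%, with 4, 10 and 5 unchanged genes called. A simulated 1.3-fold rise of the 13 glial genes in males was found by camera, with 0 other lists called. Simulated genes were drawn independently of each other, so this does not show how often camera calls lists falsely in the real data. Libraries were drawn independently too, with no effect shared by the sexes of a population and no library set apart. Recovery in the real comparisons may therefore differ. Within 1 sex most simulated changes of 1.5-fold were missed, and smaller changes of single genes were not simulated.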

Results

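The data were mRNA sequencing libraries from heads of Drosophila melanogaster, 1 library for each sex of 6 laboratory populations, 12 libraries in all. Selection had run for 117 generations, with enforced monogamy in 3 populations and polygamy in the other 3. All populations then spent 1 generation under common conditions, and heads were taken from virgin flies 4 days old. This gave 4 groups of 3 libraries: monogamous females, polygamous females, monogamous males and polygamous males. The population was the replicate within each group. The p-values of the gene tests rest on 1 spread between libraries, pooled over the 4 groups. Those for males therefore also hold the spread of the female libraries, and the reverse. The sexes of a population counted there as separate libraries, except where they were combined or the population was modelled. The p-values of the score permutations compare populations. Those of camera with the preset correlation, of Fisher's exact test and of the later contrast of glia with muscle rest on genes as units. Recovered depth ran from 34558521 to 52282995 reads per library, and 11236 genes had a value above 0 in every library. The gene tests covered 10568 genes with a mean value of 10 or more, and log2 fold changes are on the log2(value + 1) scale, which understates changes of low genes.

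The first principal component held 42.9% of the variance and separated 1 library from the rest. The female library of monogamous population 1 scored -82.6 on it. Genes of neurons lay below the other female libraries there, with a median deviation of -1.84 log2 units over the list, while ribosomal protein genes lay above them, with a median deviation of 0.55. The opsin gene ninaE took 6.23% of all signal in this library, against 3.89% to 5.41% in the others. In the quartile of genes with the longest exons the median deviation was -0.51, and in the shortest quartile it was 0.26. Its recovered depth of 45943793 reads lay within the range of the other libraries. It stayed in all main tests.

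**Figure D1:**
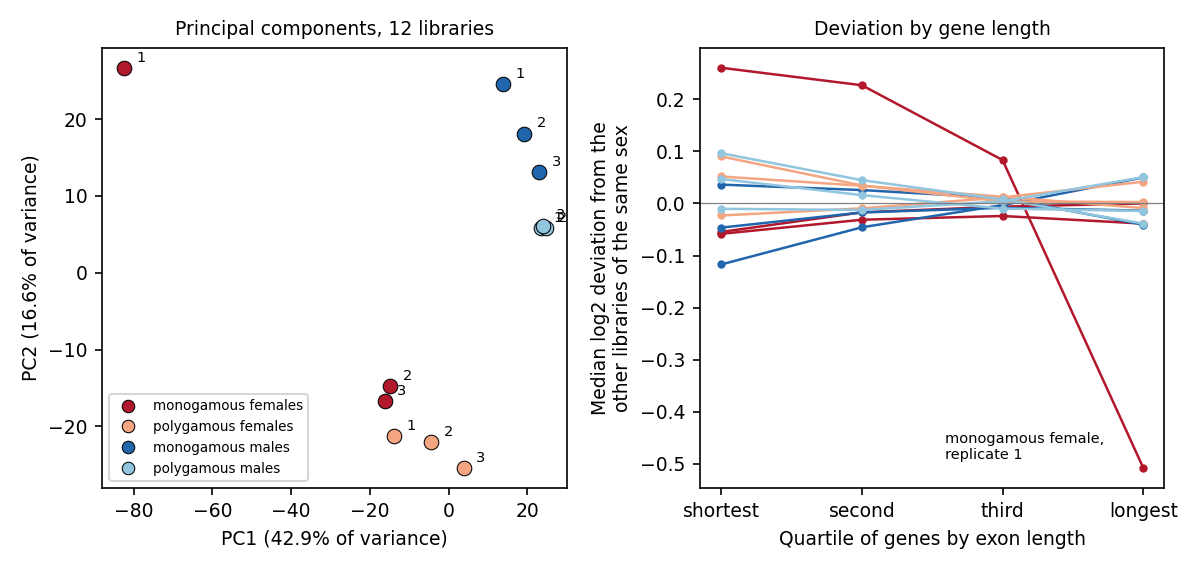
Left, the 12 libraries by their scores on the first and second principal components of log2 values (42.9% and 16.6% of the variance); right, the median log2 deviation of each library from the other libraries of the same sex in quartiles of genes by exon length. Each point or line is 1 library, and the female library of monogamous population 1 lies apart in both panels, at -82.6 on the first component.

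The first question was whether evolution under monogamy had altered expression in male heads. In males, 68 of 10568 genes differed between mating systems by limma, 57 higher and 11 lower under monogamy. Genes of pigmentation and the cuticle, of glia and of blood cells were among those that rose, and genes of a metabolic hormone and of neuropeptides were among those that fell. The ebony gene e (FBgn0000527), whose enzyme conjugates dopamine to beta-alanine in cuticle tanning and in glia, rose from 1863 ± 357 to 4542 ± 639 (mean normalised value ± SD, n = 3; log2 fold change 1.29, SE 0.17, limma adjusted p = 0.019). NimC1 (FBgn0259896), a phagocytic receptor of circulating blood cells, rose from 331 ± 39.9 to 758.7 ± 95 (log2 fold change 1.19, SE 0.12, limma adjusted p = 0.0049). Akh (FBgn0004552), the adipokinetic hormone that mobilises energy stores, fell from 1372 ± 230 to 337 ± 87.1 (log2 fold change -2.04, SE 0.36, limma adjusted p = 0.039). NPF (FBgn0027109), a neuropeptide of feeding and courtship circuits, fell from 2174 ± 66 to 1585 ± 144 (log2 fold change -0.46, SE 0.08, limma adjusted p = 0.035).

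Among the other genes that rose, y, whose product is needed for dark cuticle pigment, had a log2 fold change of 1.73. The cuticle protein gene Lcp65Ag2 rose by 1.12. CG11700 had the largest change, 3.90, but its monogamous libraries varied widely, at 499 ± 386 against 26.4 ± 2.35 (n = 3). Uncharacterised genes that rose were CG14495 (1.27), CG4950 (1.19), CG15414 (1.16), CG7509 (1.14), CG9512 (1.13), CG42711 (1.11) and CG13722 (1.09). The olfactory receptor Ir76a fell by 0.93 on the log2 scale, the neuropeptide precursor Orcokinin by 0.49 (change -0.49) and the RNA-binding protein gene yps by 0.54 (change -0.54). The snoRNA snoRNA:Psi28S-291 (-1.08) and the snoRNA host genes Uhg1 (-0.66) and Uhg5 (-0.66) were lower as well, as were CG14075 (-1.99), CR43212 (-1.01) and CG11854 (-0.84). The 2 groups of male libraries did not overlap for any of the 68 genes, and for 3358 of all 10568 genes, where chance gives 10% on average over all splits. Genes are not independent, so a single split can hold a larger share by chance. The share in other splits was not computed, here or in the comparisons below.

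**Figure D2:**
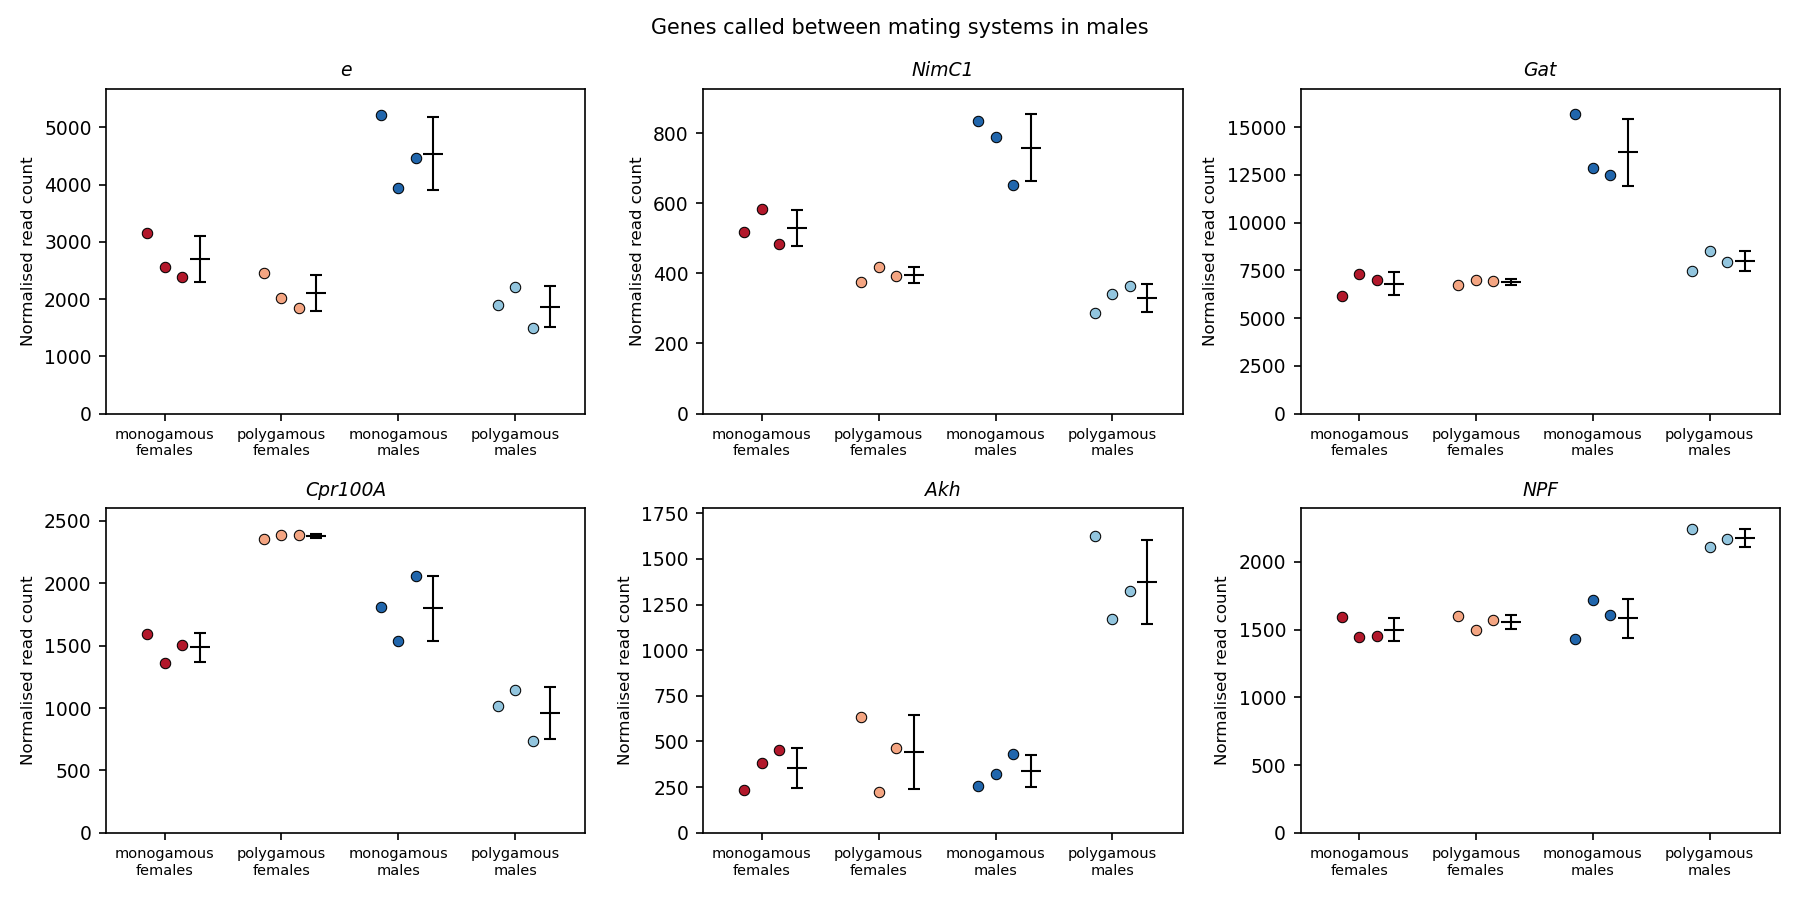
Deposited normalised values (y axes, linear scale) of 6 genes in each of the 12 libraries by group; points are libraries, the horizontal mark is the mean and the bar ± 1 SD (n = 3). In males e, NimC1, Gat and Cpr100A lie higher under monogamy and Akh and NPF lower, with Akh at 337 ± 87.1 against 1372 ± 230.

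Of 33 gene lists fixed before the data were examined, camera called 4 higher and 3 lower in monogamous males. Glial genes were higher as a group, with 12 of 13 members positive and a median log2 fold change of 0.26 (camera adjusted p = 1.16e-08; adjusted p = 0.0619 with an estimated correlation). In this list 3 members rose over all genes tested and 7 when adjusted over the list alone. They were Gat, the GABA transporter of astrocytes (0.77), nrv2, a sodium pump subunit (0.52), and Mdr65, a transporter of the blood-brain barrier (0.36). Cuticle protein genes had a median of 0.33, with 38 of 47 members positive (camera adjusted p = 2.07e-08; adjusted p = 0.0931 with an estimated correlation). Cpr100A (0.91) and Lcp65Ag2 rose over all genes, and 12 members did when adjusted over the list alone. Hemocyte genes had a median of 0.22 over 11 members (camera adjusted p = 0.00053; adjusted p = 0.154 with an estimated correlation). NimC1 and Hml, a clotting factor (0.86), rose, while PPO2, a phenoloxidase of crystal cells, had a value of -0.79 that did not pass over all genes (limma adjusted p = 0.24). When adjusted over the list alone, 2 hemocyte genes rose and 1 fell. Heat shock genes had a median of 0.26 over 15 members (camera adjusted p = 0.000492; adjusted p = 0.525 with an estimated correlation), and none passed over all genes, 1 when adjusted over the list alone. Hsp27 stood at 0.86 (limma adjusted p = 0.098).

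Neuropeptide genes were lower in monogamous males, with a median of -0.20 over 32 members (camera adjusted p = 0.000463; adjusted p = 0.154 with an estimated correlation). Over all genes 2 fell, Akh and NPF, and when adjusted over the list alone 10 fell and 1 rose. Mip (-0.42) and Dsk (-0.46), the sulfakinin of satiety, did not pass over all genes (limma adjusted p = 0.12 and 0.13). Odorant receptor genes had a median of -0.29, with 6 of 49 positive (camera adjusted p = 2.85e-06; adjusted p = 0.333 with an estimated correlation). No odorant receptor passed over all genes, and when adjusted over the list alone Or59c rose (0.94) and Or65a fell (-0.43). Ribosomal protein genes had a median of -0.14, with 9 of 80 positive and 0 past the limma threshold (camera adjusted p = 0.000565; adjusted p = 0.851 with an estimated correlation). The fry test called glia, cuticle protein and hemocyte genes higher, and neuropeptide and dosage compensation genes lower. Single members of lists that camera did not call also rose: santa-maria, a carotenoid uptake receptor of the phototransduction list (0.58), Cyp318a1 among cytochromes P450 (0.77) and Ugt301D1 among UDP-glycosyltransferases (0.72). The ribosomal call ended without polygamous population 1, where its median was -0.06 and 9 lists were called. The number of members past the limma threshold depended on the setting. After upper-quartile rescaling it was 1 glial, 0 cuticle protein and 1 neuropeptide gene. When the female library of monogamous population 1 was left out, 8 glial, 4 hemocyte and 4 heat shock genes were higher, 8 cuticle protein genes were higher and 1 lower, and 8 neuropeptide genes were lower.

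These male counts depended on single populations. Without monogamous population 1, 2 or 3 the count was 466, 3 and 12, and without polygamous population 1, 2 or 3 it was 0, 0 and 8, the spread being shared with the remaining libraries. Leaving out only the female library of monogamous population 1 gave 861 genes (488 higher and 373 lower), all 68 among them. edgeR called 114 genes and DESeq2 400.

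In females the same comparison called 0 of 10568 genes by limma, with 1866 at an unadjusted p under 0.05. In males that unadjusted count was 1216, so the numbers of called genes do not show a wider change in males than in females. Counts of 0 by edgeR and 270 by DESeq2 (209 higher and 61 lower under monogamy) stood beside it. The yolk protein genes stood higher in monogamous females without passing: Yp1 (FBgn0004045) measured 961008 ± 157998 against 559882 ± 51344 (n = 3; log2 fold change 0.77, SE 0.13, limma adjusted p = 0.15). Yp2 (0.81) and Yp3 (0.84) lay in the same direction. Yolk proteins together took 4.79% ± 0.994 of all signal in monogamous and 2.72% ± 0.232 in polygamous females (SD, n = 3), against 0.0115% and 0.0136% in males. The 10 genes with the smallest p, none of which passed, were CG31915 (0.68), CG11700 (4.67), Jhbp5 (-0.98), the cytochromes Cyp6d2 (1.72) and Cyp4ac2 (1.07), Obp83g (-1.04), DhpD (0.46), magu (0.45), Yp1 and CG7720 (0.48). Their limma adjusted p-values ran from 0.11 to 0.15. The 2 groups of female libraries did not overlap for 2492 genes, where chance gives 10% on average over all splits.

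Camera called 8 of the 33 lists in females, 5 higher and 3 lower under monogamy, and none held with an estimated correlation (adjusted p = 0.587 to 0.606 with an estimated correlation for these 8). Genes of yolk and of the female head fat body were higher, with all 8 positive and a median of 0.73 (camera adjusted p = 7.22e-05), and 4 passed when adjusted over the list alone. Cytochrome P450 genes had a median of 0.16 over 77 members (camera adjusted p = 0.00266), with 5 higher and 1 lower when adjusted over the list alone, and 0.08 without the female library of monogamous population 1. Lipid storage and lipase genes had a median of 0.17 over 20 members (camera adjusted p = 0.0177), among them AkhR, the receptor of the adipokinetic hormone (0.50, limma adjusted p = 0.15), and their median was 0.07 without that library. Thoracic muscle genes had a median of -0.23 over 21 members (camera adjusted p = 0.0311). Ribosomal protein genes had a median of 0.25, and 0.09 without that library, and proteasome genes 0.21 and 0.04. Neuronal genes had a median of -0.77, and -0.12 without it. Genes of courtship and mating behaviour had a median of -0.31 (camera adjusted p = 0.0241), and -0.05 without it, where the call ended (camera adjusted p = 0.425). Without polygamous population 3 the lipid, muscle and courtship calls ended and 5 lists remained, without monogamous population 3 the lipid and muscle calls ended with 7 lists called, and without monogamous population 2 the muscle call did with 8 called. Without monogamous population 1 the neuronal and courtship calls ended, with 10 lists called, and the medians were -0.12 and -0.05, 0.08 for P450, 0.07 for lipid, 0.09 for ribosomal and 0.04 for proteasome genes. The P450 median was 0.10 without polygamous population 2, and the lipid and muscle medians 0.05 and -0.14 without polygamous population 3.

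Without monogamous population 1, 2 or 3 the female count was 5, 1 and 5, and it was 0 without each polygamous population. CG11700 passed without monogamous population 1 (3.93) and without population 3 (5.22). Other genes of these small sets, picked out because they passed, were Jhbp5 (-0.80), mRpS16 (0.68), Cox11 (-0.52) and an unnamed gene (-0.35) without population 1, and CG3823 (0.75), CG4660 (0.96), Pdk1 (-1.15) and CG18563 (-1.49) without population 3.

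With both sexes of a population averaged, 0 of 10568 genes differed between the 3 monogamous and 3 polygamous populations by limma, with 1496 at an unadjusted p under 0.05. On reads summed over the sexes of a population, a measure unlike the mean of log2 values, edgeR called 0 and DESeq2 386. Lowest in p were the acetylcholine receptor subunit gene nAChRbeta3 (0.76) and yellow-c (0.73), both at a limma adjusted p of 0.12, followed by CG4950 (0.76), the hemocyte genes Hml (0.63) and NimC1 (0.80), Or45b (-0.98), CG11700 (4.28), CG32645 (0.58), CG31915 (0.50) and lectin-37Db (-2.53), at a limma adjusted p of 0.23. The population means did not overlap for 3031 genes, where chance gives 10% on average over all splits. Across genes, the mating difference in females and that in males had a Pearson correlation of 0.377 and a Spearman correlation of 0.344. Genes are not independent replicates, and both sexes of a population share its history, so a value above 0 arises for other groupings of the populations too: the highest of the other 9 was 0.382.

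The sexes differed far more than the mating systems. Over all populations 3119 of 10568 genes differed by limma, 2139 higher in males and 980 higher in females. The genes with the largest differences were those of dosage compensation and yolk. The noncoding RNA lncRNA:roX1 (FBgn0019661), part of the complex that raises X transcription in males, measured 71469 ± 4519 in monogamous males and 293 ± 36.8 in monogamous females (n = 3; log2 fold change 7.85 over all populations, SE 0.07, limma adjusted p = 1.8e-13), and lncRNA:roX2 had a fold change of 7.06. The yolk protein genes were lower in males, Yp1 by -8.66 (SE 0.09, limma adjusted p = 1e-12), Yp2 by -8.49 and Yp3 by -7.59. Male heads also had more atk (4.12), brv3 (3.74), Cyp4d21 (2.87), sxe2 (2.81), Cyp4d14 (2.63), Cyp313a1 (2.50), fiz (2.42), the cuticle protein gene Cpr76Ba (2.40), CG14195 (3.28) and CG30088 (3.18). Female heads had more P5CDh2 (-4.14), snoRNA:Psi28S-1232 (-3.62), the unconventional myosin gene Myo61F (-2.92), CG5246 (-5.08), CG10814 (-4.12), CG15399 (-3.71), CG31465 (-3.54), CG34148 (-3.08) and CG14626 (-2.74). Of the genes of the sex pathway, msl-2, the male-specific dosage compensation gene, was higher in males (0.63), as was the takeout gene to of the male fat body (0.42), and fit was higher in females (limma adjusted p = 0.00017). The sex determination genes Sxl (-0.05), tra (-0.14), dsx (0.37) and fru (0.06) did not pass, and without the female library of monogamous population 1 Sxl (-0.38), tra (-0.31) and fru (-0.21) were lower and dsx (0.22) higher in males. The value of fru was also negative after TMM (-0.06) and upper-quartile rescaling (-0.09), without passing. The male and female libraries did not overlap for 2138 genes, 1694 of them called.

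Ribosomal protein genes were lower in males almost without exception, with 79 of 80 past the limma threshold and a median of -0.79 (camera adjusted p = 1.61e-60; adjusted p = 0.25 with an estimated correlation). RpS20 (-1.10) was among them, and 79 passed when adjusted over the list alone. They took 7.91% ± 1.56 of all signal in monogamous females, 6.59% ± 0.636 in polygamous females, 3.96% ± 0.196 in monogamous males and 4.31% ± 0.414 in polygamous males (SD, n = 3). Of 8 yolk and female fat body genes 5 were lower in males, also when adjusted over the list alone (median -1.35, camera adjusted p = 1.08e-09; adjusted p = 0.153 with an estimated correlation). Dosage compensation genes were higher in males, 6 of 8 over all genes and 7 when adjusted over the list alone (median 0.30, camera adjusted p = 3.26e-05), and theirs was the 1 list call that held with an estimated correlation (adjusted p = 0.0491 with an estimated correlation). It did not hold there without the female library of monogamous population 1 (adjusted p = 0.329 with an estimated correlation). Male head fat body genes were higher in 3 of 6 cases, also when adjusted over the list alone (median 0.66, camera adjusted p = 0.0392; adjusted p = 0.609 with an estimated correlation). The male fat body call ended without that female library (camera adjusted p = 0.127), without monogamous population 1 (12 lists called) or 3 (11 lists called) and with populations as a block (11 lists called).

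**Figure D3:**
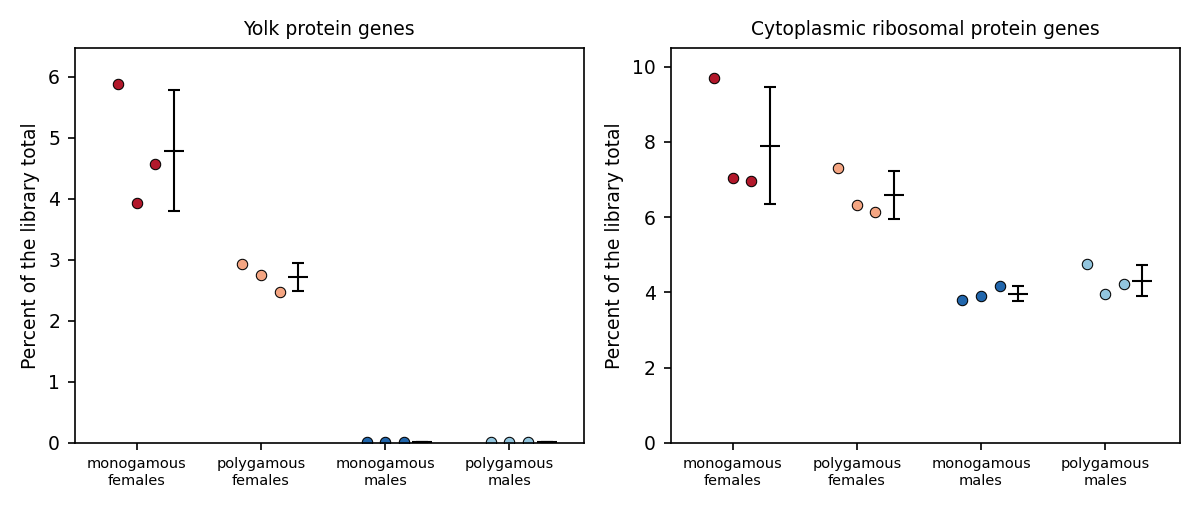
Percent of all deposited signal taken by the yolk protein genes (left) and by ribosomal protein genes (right) in each library by group; points are libraries, the horizontal mark is the mean and the bar ± 1 SD (n = 3). Yolk protein genes took 4.79% ± 0.994 in monogamous and 2.72% ± 0.232 in polygamous females, and ribosomal protein genes took a larger share in every female than in any male library.

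Glial genes were higher in males in 9 of 13 cases, 10 when adjusted over the list alone (median 0.38, camera adjusted p = 0.00157; adjusted p = 0.25 with an estimated correlation), including Gat (0.60) and alrm (0.73). Neuronal genes were higher in 5 of 15, also when adjusted over the list alone (median 0.67, camera adjusted p = 0.035; adjusted p = 0.791 with an estimated correlation), such as ChAT (0.54) and VGlut (0.55), which make and load acetylcholine and glutamate, and in 14 of 15 without the female library of monogamous population 1, at a median of 0.37 (0.35 without monogamous population 1 as a whole). Biogenic amine genes were higher in 7 of 27 and lower in 1, and higher in 11 and lower in 1 when adjusted over the list alone (median 0.34, camera adjusted p = 0.014; adjusted p = 0.609 with an estimated correlation). Without that library 19 were higher and 0 lower, at a median of 0.32. Tbh (0.54), which makes octopamine, and the transporters Vmat (0.52) and DAT (0.35) were among them. Genes of courtship and mating behaviour were higher in 10 of 27, also when adjusted over the list alone (median 0.45, camera adjusted p = 0.0175; adjusted p = 0.791 with an estimated correlation), including the pheromone-binding gene lush (0.81) and the receptor gene Or47b (1.06). Without that library 15 of the courtship genes were higher and 1 lower, at a median of 0.26, and the list call ended (camera adjusted p = 0.0815), as it did without the whole of monogamous population 1, at a median of 0.24.

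Antimicrobial peptide genes were lower in males in 7 of 21 cases, 8 when adjusted over the list alone (median -0.86, camera adjusted p = 5.09e-06; adjusted p = 0.609 with an estimated correlation), among them BomS3 (-0.58), Dso1 (-0.84) and BomBc2 (-0.98). Their median was -0.52 without monogamous population 1. Thoracic muscle genes were lower in 8 of 21 and higher in 1, and lower in 9 and higher in 1 when adjusted over the list alone (median -0.27, camera adjusted p = 5.09e-06; adjusted p = 0.549 with an estimated correlation). Mlc1 (-0.64) and Mhc (-0.38), the myosin chains, were among these. The list also held arg, an arginase, which counts among the lower genes (-2.54) but whose place among muscle markers is uncertain. Odorant-binding protein genes went both ways, 9 higher and 11 lower of 35, and 9 and 12 when adjusted over the list alone (median -0.19, camera adjusted p = 0.0122; adjusted p = 0.661 with an estimated correlation), with Obp56e (-2.65) and Obp56a (-2.23) the lowest in p. Their median was -0.09 without the female library of monogamous population 1, and -0.12 without monogamous population 1 or polygamous population 3. Cuticular hydrocarbon and pheromone genes were lower in 4 of 11 and higher in 1, also when adjusted over the list alone (camera adjusted p = 0.0375; adjusted p = 0.609 with an estimated correlation). Their median was -0.21 and their mean 0.09, of opposite sign. Cyp4g1, the enzyme that completes cuticular hydrocarbons, stood at 2.89, while bgm (-0.70) and FASN2 (-0.92) were lower. That call ended without the same library (3 higher and 5 lower, camera adjusted p = 0.0657), without monogamous population 1 or 3, and without polygamous population 3, where the neuronal call ended too and 10 lists were called. Neither this list nor the odorant-binding list was called after TMM rescaling.

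In the remaining 21 lists camera found no difference between the sexes at its threshold, though single members passed. Without the female library of monogamous population 1 it called the odorant receptor (camera adjusted p = 0.0234), phototransduction (0.0401) and proteasome lists (0.0162), with adjusted p-values of 0.452, 0.452 and 0.551 with an estimated correlation. The fry test, which does not compare a list with other genes, called 14 lists for the sexes, 11 higher and 3 lower in males. It did not call the antimicrobial peptide, odorant-binding protein and cuticular hydrocarbon lists (fry adjusted p = 0.0945, 0.081 and 0.081), and it called sex determination, phototransduction, neuropeptide, heat shock and cuticle protein genes higher. Neuropeptide genes were higher in 14 of 32 and lower in 2, with Mip (0.46) and AstA (0.34) higher and the insulin-like Ilp6 (-0.99) and Ilp3 (-0.65) lower in males. Insulin, juvenile hormone and ecdysone genes were higher in 4 of 21 and lower in 1, with Jhe (1.65), the juvenile hormone esterase, and Thor (-1.13), the translation repressor downstream of insulin. Lipid storage and lipase genes were higher in 3 of 20 and lower in 4, with AkhR (-1.15), Lsd-1 (-1.03) and Lip2 (1.52). Cytochrome P450 genes were higher in 15 of 77 and lower in 12, glutathione and UDP transferase genes in 12 and 4 of 57, cuticle protein genes in 10 and 8 of 47, and hemocyte genes in 2 and 4 of 11. The odorant receptor genes were higher in 5 of 49 and lower in 6 (Or88a 0.98), gustatory receptor genes higher in 3 of 20, ionotropic receptor genes in 2 of 26, and pickpocket channel genes higher in 2 of 20 and lower in 3. Phototransduction genes were higher in 7 of 32, and in 20 without the female library of monogamous population 1. Clock genes were higher in 2 of 16, heat shock genes in 4 of 15, and sex determination genes in 3 of 13. Without that library the clock genes were higher in 7 and lower in 1, heat shock genes higher in 11, and sex determination genes higher in 4 and lower in 3. In the same fit insulin, juvenile hormone and ecdysone genes were higher in 12 and lower in 4, immune recognition and signalling genes in 11 and 2, glutathione and UDP transferase genes in 21 and 4, and lipid storage and lipase genes in 5 and 4. Immune recognition and signalling genes were higher in 3 of 29 and lower in 1 (TotC -1.15), testis genes in 1 and 2 of 9, and ovary genes in 2 and 1 of 13. Of the gut serine proteases 1 of 15 was lower. For nuclear genes of oxidative phosphorylation (69) and the proteasome (31) 0 members passed by limma, and 20 and 19 were higher in males without that library. The oxidative phosphorylation list went the other way in other settings: after TMM rescaling 0 members were higher and 4 lower, at a median of -0.11 (camera adjusted p = 0.00803), and camera also called it lower in males without monogamous population 2 or 3 and without polygamous population 1. Of the lists with too few members, Acp24A4 (-1.05) and Est-6 (0.34) of the accessory gland passed and Acp63F (-0.12) did not, and of the salivary list Sgs1 (1.06), Amyrel (0.16) and Nplp3 (-0.03) did not.

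How many genes were higher or lower in males depended on scaling. The median log2 difference over all genes was 0.13 in the deposited values, 0.01 after TMM rescaling and -0.02 after upper-quartile rescaling. The split was 836 higher and 1522 lower after TMM rescaling and 528 and 1286 after upper-quartile rescaling, 828 and 1567 by edgeR, and 1121 and 1611 by DESeq2. Leaving yolk protein genes out of the library totals gave 1380 and 1158, and leaving out yolk and ribosomal protein genes gave 847 and 1210. Without the female library of monogamous population 1 the count was 5460 (4252 and 1208). Without monogamous population 1 it was 5247, and without polygamous population 1, 2 or 3 it was 1908, 1709 and 1923. Ribosomal protein genes remained lower under both rescalings (80 and 79 of 80), while of the dosage compensation genes 3 passed, and of the phototransduction genes 2 and 0. The balance turned towards females for cytochrome P450 genes, with 11 higher and 18 lower in males after TMM and 6 and 15 after upper-quartile rescaling, for immune recognition and signalling genes (0 and 3 in both), and for sex determination and clock genes (0 and 1 in both). Glutathione and UDP transferase genes stood at 5 and 5, and 1 and 5, cuticle protein genes at 9 and 10, and 8 and 9, insulin, juvenile hormone and ecdysone genes at 4 and 2, and 2 and 2, gustatory receptor genes at 1 and 1 in both, ionotropic receptor genes at 2 and 1, and 1 and 1, and ovary genes at 0 and 1 in both. Neuropeptide genes stood at 10 and 3, and 4 and 2, heat shock genes at 3 and 1, and 1 and 0, lipid storage and lipase genes at 3 and 6, and 2 and 6, and odorant-binding protein genes at 7 and 12, and 4 and 11. Of the lists higher in males, glial genes stood at 7 and 1, and 5 and 0, while 2 and 3 neuronal, 7 and 4 biogenic amine and 6 and 5 courtship genes were higher. Thoracic muscle genes were lower in 13 and 11 cases.

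Within the monogamous populations 2336 genes differed between the sexes by limma, 1498 higher and 838 lower in males, and within the polygamous populations 821 did, 498 higher and 323 lower. After TMM rescaling the splits were 558 and 1211, and 173 and 470, and after upper-quartile rescaling 324 and 1101, and 123 and 271. By edgeR they were 561 and 1243, and 174 and 490, and by DESeq2 901 and 1415, and 340 and 660. These counts depended on single libraries: without the female library of monogamous population 1 they were 4024 and 3654. Without monogamous population 1, 2 or 3 the monogamous count was 3399, 1284 and 893, without polygamous population 2 it was 1398, and without population 3 it was 1569. With only the 6 libraries compared in each fit the order turned, with 534 genes under monogamy and 2674 under polygamy. The polygamous counts without monogamous populations were 3743, 385 and 418, and without polygamous populations 186, 130 and 158.

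The test of whether the sex difference itself differed between mating systems called 0 of 10568 genes by limma, with 576 at an unadjusted p under 0.05. By edgeR it called 0 and by DESeq2 63. The sexes of 1 population share that population by the labels, and with populations as a block in limma 9 genes passed. All had a positive difference, so that males stood higher relative to females under monogamy than under polygamy. These genes, named because they passed, were the cuticle protein genes Acp1 (3.11), Cpr97Eb (1.58), the chitin deacetylase gene Cda4 (1.34), and Vajk3 (3.01), CG8736 (3.29), CG7203 (2.06), CG3713 (1.32), CG11458 (2.26) and CG7214 (3.31). In the unblocked test the 10 genes with the smallest p, none of which passed (limma adjusted p = 0.10), included Cpr100A (1.59), Cpr97Ea (3.03), Cpr49Ae (0.76), Acp1, Cda4, the chitin deacetylase serp (1.64), the collagen gene Col4a1 (0.91), Ugt301D1 (0.67), CG8736 and CG13722 (1.82). Cpr100A measured 1488 ± 117 in monogamous and 2379 ± 16.7 in polygamous females, and 1800 ± 261 in monogamous and 964 ± 208 in polygamous males (n = 3). Yp1 (-1.07) and Yp2 (-1.18) leaned towards a larger female excess under monogamy. Without the female library of monogamous population 1, 9 genes passed: Yp1 (-0.94) and Yp2 (-0.99) lower, and Cpr49Ae (0.70), Cpr100A (1.65), Ugt301D1 (0.65), Col4a1 (0.99), nemy (0.55), CG1537 (0.76) and CG4462 (0.51) higher. The same libraries gave 0 genes after TMM rescaling by limma and 0 by edgeR, with 934 and 948 at an unadjusted p under 0.05. With populations as a block and the deposited scaling they gave 334 genes, 260 higher and 74 lower. The count thus depended on the scaling and on the block. Without monogamous population 1 as a whole, and without the block, vkg (0.70) alone passed. The population differences did not overlap for 2328 genes, where chance gives 10% on average over all splits, so this count is no sign of an effect by itself.

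A further question was whether monogamy shifted expression of sex-biased genes towards the female or the male state. Each library was given a score, the median centred log2 value of the 980 female-biased genes minus that of the 2139 male-biased genes. These sets came from the same libraries, by the comparison of the sexes. In females the score was 0.572 ± 0.248 under monogamy and 0.309 ± 0.0967 under polygamy (SD, n = 3), a difference of 0.263 with an exact two-sided permutation p of 0.2. Males scored -0.460 ± 0.0604 and -0.412 ± 0.102, a difference of -0.048 (n = 3, exact two-sided permutation p = 0.7). The distance between the sexes of a population was 1.03 ± 0.294 under monogamy and 0.722 ± 0.0296 under polygamy, a difference of 0.311 (n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Without the female library of monogamous population 1 the female difference was 0.133 and the difference in distance 0.141. The sets changed these values too. With sets called in the polygamous populations the difference in distance was 0.134 (n = 3, exact two-sided permutation p = 0.4), that in females 0.143 and that in males 0.0085. With sets called in the monogamous populations they were 0.484, 0.361 and -0.123. With sex-biased genes of at least 2-fold the male difference was -0.166 (n = 3, exact two-sided permutation p = 0.1). Female-biased genes had a median mating difference of 0.21 in females, 79.2% of them higher under monogamy (camera p = 1.4e-18; p = 0.112 with an estimated correlation), and -0.03 in males. Male-biased genes had a median of -0.07 in females and 0.02 in males, with 37.7% and 54.8% higher under monogamy. With the sets and tests made without the female library of monogamous population 1, the female-biased median in females was 0.08 (p = 0.107 with an estimated correlation), and the male-biased medians were -0.05 in females and -0.0039 in males.

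**Figure D4:**
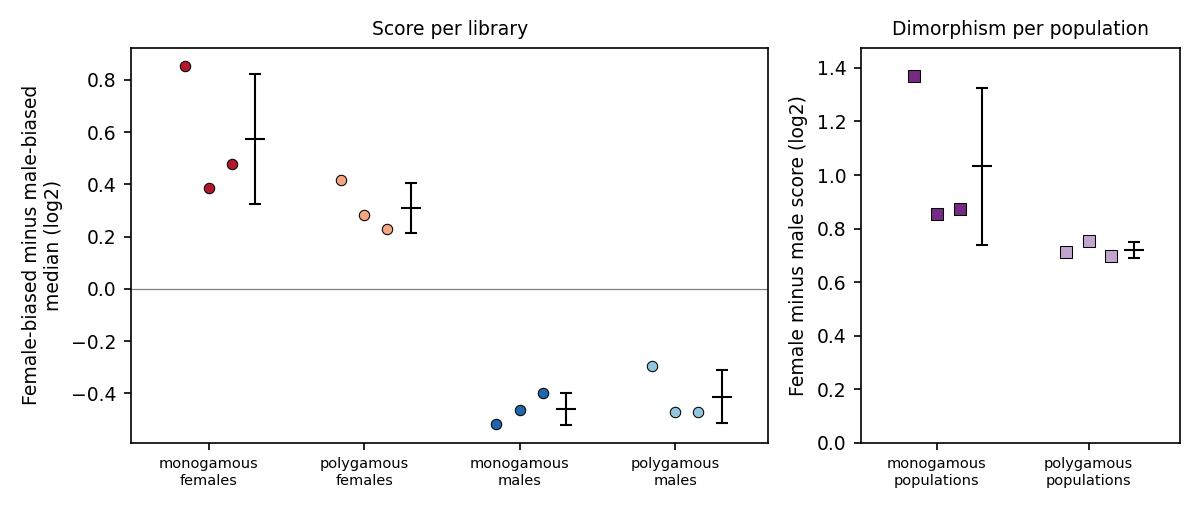
Left, the score of each library (median centred log2 value of female-biased minus male-biased genes) by group; right, the female minus male difference in score of each population; points are libraries or populations, the horizontal mark is the mean and the bar ± 1 SD (n = 3). Female scores were 0.572 ± 0.248 under monogamy and 0.309 ± 0.0967 under polygamy, and the population difference was 1.03 ± 0.294 and 0.722 ± 0.0296.

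X-linked genes made up 16.6% of 10130 tested genes with a known chromosome. Among genes higher in monogamous males 14 of 54 were X-linked (25.9%, odds ratio 1.77, Fisher's exact p = 0.068, adjusted p = 0.090 over 4 tests), and among those lower 1 of 11 (odds ratio 0.503, exact p = 1). For the higher genes the odds ratio was 1.35 after TMM rescaling and 1.16 without the female library of monogamous population 1 (85 of 456, Fisher's exact p = 0.22), where that of the lower genes was 0.945. Of the genes higher in female heads 218 of 942 were X-linked (23.1%, odds ratio 1.59, Fisher's exact p = 5.0e-08, adjusted p = 2.0e-07). Of those higher in male heads 373 of 2041 were X-linked (18.3%, odds ratio 1.16, Fisher's exact p = 0.021, adjusted p = 0.043), an odds ratio that was 1.48 after TMM rescaling, chosen after seeing the data, and 1.00 without the female library of monogamous population 1. Genes are not independent, so these p-values describe the lists only.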

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

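Dixon's gap test was run 21 times on measures and 154 times on single genes, each time within the 6 libraries of a sex or the 6 populations. Most measures and all genes were tested in each sex, and chance alone marks about 1 in 20 tests. Some of the tests below were chosen only after the result was seen. These were the tests of exon length, body tissue lists, the male partner, rescaling, the contrast of glia with muscle and the run without a single library. Of the 21 tests of measures 6 stood out, against 1.05 expected by chance, and the female library of monogamous population 1 was the extreme sample in 5 of the 6. The share of signal in the 10 most abundant genes was 18.1% there (gap over range 0.818), the ninaE share 6.23% (0.696), the score on the first component -82.6 (0.767), that on the second component highest (0.796), and the ribosomal protein share 9.71% (0.668). The distance between the sexes was largest in monogamous population 1, at 1.37 (0.740). Among the 154 tests of single genes 6 stood out, against 7.7 expected by chance. In that female library Sxl (0.894), tra (0.781), dsx (0.846) and fru (0.899) were lowest. In other libraries, yps was highest in the female library of polygamous population 1 (0.712) and Myo61F lowest in the male library of monogamous population 1 (0.738).

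In 8 of 33 lists camera found a different mating effect in the sexes, and none of these held with an estimated correlation. The median of the interaction was -0.309 for yolk and female fat body genes (adjusted p = 0.694 with an estimated correlation), 0.338 for biogenic amine genes (adjusted p = 0.694 with an estimated correlation), 0.517 for heat shock genes (adjusted p = 0.751 with an estimated correlation) and -0.375 for ribosomal protein genes (adjusted p = 0.751 with an estimated correlation). It was -0.144 for proteasome genes (adjusted p = 0.894 with an estimated correlation), 0.244 for glial genes (adjusted p = 0.563 with an estimated correlation), 0.765 for neuronal genes (adjusted p = 0.751 with an estimated correlation) and 0.352 for cuticle protein genes (adjusted p = 0.273 with an estimated correlation). Without the female library of monogamous population 1 the medians were 0.189 for neuronal, 0.019 for proteasome, 0.05 for biogenic amine and -0.219 for ribosomal protein genes, and the proteasome and amine calls ended. The same 4 medians were 0.186, 0.028, 0.011 and -0.185 without monogamous population 1 as a whole. The yolk median was -0.622 without polygamous population 2, that of heat shock genes 0.278 without monogamous population 3, and that of proteasome genes -0.225 and -0.239 without monogamous population 2 and 3.

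The female library of monogamous population 1 stands apart from the other 11. RNA from ovary, thoracic muscle or gut did not show in the list medians of its deviation, the highest of the 3 being -0.119. These medians were not corrected for exon length, so a loss of long transcripts could hide a gain, and this explanation is not excluded. A difference of the same size in both sexes of the population is argued against. The male partner's deviation had a slope of only 0.0445 on that of the female library. Their correlation was 0.0908, so a smaller part shared by both sexes is not excluded. A bias against long transcripts, as partial degradation or priming could give, may account for part: the deviation correlated with exon length at a Spearman rho of -0.384, outside the range of the other libraries (-0.271 to 0.318). It is not the whole, because the SD of the deviations was 0.836 before and 0.746 after the length trend was removed, against at most 0.435 in the others. What else sets this library apart stays open, including a biological difference of these females, which was not tested.

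Camera called the lists of glial, hemocyte and cuticle protein genes higher in monogamous males, with 3 of 13, 2 of 11 and 2 of 47 members past the limma threshold, and none of these calls held with an estimated correlation (adjusted p = 0.0619, 0.154 and 0.0931 with an estimated correlation). Library scaling is argued against as the source of the list medians. The lowest of the 3 under TMM or upper-quartile rescaling was 0.195, though 1, 2 and 0 members passed under the latter. A lower share of neuronal RNA with every other cell type raised alike is argued against by the medians only. Neuronal genes had a median of 0.05, and glia exceeded thoracic muscle by 0.320. The permutation p of 0.0108 for glia against muscle came from shuffling genes between the lists. It treats genes as independent and does not measure spread between populations. Another time of day at collection stays open: clock genes of opposite phase differed between mating systems by 0.506 in males (SE 0.280, exact permutation p = 0.2) and by 0.654 in females (SE 0.132, exact permutation p = 0.1, the smallest possible), so time of day and mating system cannot be told apart for these genes. Maturity after eclosion was not tested. An evolved difference in these tissues is the biological hypothesis, and likewise remains untested.

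Ribosomal protein genes were lower in male than in female heads, 79 of 80 by limma (adjusted p = 0.25 with an estimated correlation for the list). A trend on transcript length is argued against, as 125 other genes had a median sex difference of -0.016. These were the nearest genes on length and abundance combined, with a median exon length of 956 bp against 935.5 bp. How near they lay in abundance was not measured, so a trend on abundance is not excluded. Library scaling is argued against as well, with a highest median of -0.899 under rescaling, and so is the single female library, with a median of -0.703 without it. A difference in the makeup of male and female heads may underlie the pattern and is a hypothesis that was not tested here.

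Other groupings of the same libraries were refitted. For comparisons of 3 against 3 there are 10 splits, too few for a share under 0.05. In males the real split gave 68 genes and the highest other 0, with 1 split as large. In females the real and highest other values were 0 and 0 (10 splits as large), for both sexes averaged 0 and 1 (10), for the interaction 0 and 0 (10), for the sexes under monogamy 2336 and 1 (1 split), under polygamy 821 and 0 (1 split), and for the correlation between the female and male mating effects 0.377 and 0.382 (2 splits). List calls by camera numbered 8 in females, with 12 the highest other (8 splits as large), and 7 in males, with 14 the highest other (7 splits). For the sexes over all populations, 1 of 100 splits drawn reached the real 3119 genes, the next being 5, so chance can be excluded there. The 12 list calls for the sexes were reached in 21 of 100 splits, with up to 15, so chance cannot be excluded for their number. The 13 drawn splits that part all 6 population pairs, as the real one does, gave at most 1 gene and 13 lists.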

How the results depend on the processing

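Array weights, TMM rescaling for X linkage and all fits without the female library of monogamous population 1 alone were chosen after seeing the data. Pseudocounts and the filters on low values kept every gene count within 1.5 times its main value. Where a value moved, the cause was not tested, beyond fewer libraries in fits that leave some out.

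Genes differing in males (68) numbered 109 with TMM, 36 with upper-quartile rescaling, 45 without variance trend, 114 by edgeR, 400 by DESeq2, 177 at a threshold of 0.10, 423 with only the 6 male libraries, 1813 with array weights, and 869 (TMM) and 883 (edgeR) without the female library. In females (0) they numbered 270 by DESeq2, 219 with array weights, and 8 (TMM) and 7 (edgeR) without the library. For both sexes averaged (0) they numbered 386 by DESeq2 on summed reads, 171 with 12 separate libraries and 69 with population as a random effect. For the sexes (3119) they were 1814 with upper-quartile rescaling and 6178 with array weights. Under monogamy (2336) they were 1425 with upper-quartile rescaling, 3547 at 0.10, 534 with only 6 libraries and 5204 with array weights, and under polygamy (821) 394, 1402, 2674 and 4019, with 1960 (TMM) and 1946 (edgeR) without the library. The interaction (0) gave 63 by DESeq2 and 81 with array weights.

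With the replicate block, 1 gene passed in females (CG11700) and 9 in the interaction, and no other count moved by over 1.5 times; in males it gave 101. For comparisons of mating systems this block was the library number, and for the sexes and the interaction it was the population. The same number in different mating systems names different populations, whose deviations correlated at -0.124 to 0.146. The blocked mating counts, CG11700 among them, therefore do not rest on a pairing of populations. With the replicate block and without the library, counts were 482 in females, 1345 in males, 4 for both sexes, 6524 for the sexes, 5173 under monogamy, 5452 under polygamy and 334 in the interaction.

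Leaving out 1 population, or that library, gave 1 to 5 genes in females where any passed, 0 to 861 in males, 1709 to 5460 for the sexes, 893 to 4024 under monogamy, 130 to 3743 under polygamy and 1 to 9 in the interaction where any passed. The list count in females was 5 to 11 (main 8), lowest without polygamous population 3 and highest without the library. The score difference in males ran from -0.127 to 0.018 over fits without 1 population, reversed without polygamous population 1, and reversed to 0.0085 with sex-biased genes taken from polygamous populations; it was -0.123 with those from monogamous populations and -0.166 with those of at least 2-fold (exact permutation p = 0.1, the smallest possible), against -0.048 (exact permutation p = 0.7). The correlation of mating effects was 0.265 without monogamous population 2, 0.421 without the library and 0.443 at a mean of 50 or more. The X odds ratio of genes higher in males was 1.06 at a threshold of 0.10, 1.07 at a mean of 50 or more and 1.00 without the library. With an estimated correlation 0 lists were called in females, 0 in males and 1 for the sexes; fry called 0 in females. For fru the sex difference (0.06) reversed to -0.22 with array weights, -0.33 (TMM), -0.34 (edgeR) and -0.21 (replicate block) without the library, and ran from -0.21 (without monogamous population 1) to 0.20 (without population 3). Score differences in females stayed positive, from 0.097 to 0.449, and those in distance from 0.134 to 0.516.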

Other observations

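All values in this part were looked at after the comparisons had been seen, and none carries a test beyond the one named. Expression of Obp99a, an odorant-binding protein, stood higher under monogamy in both sexes without passing: 15824 ± 2125 against 7334 ± 2860 in females and 9493 ± 533 against 4326 ± 733 in males (SD, n = 3; log2 fold changes 1.19 and 1.15, limma adjusted p = 0.20 and 0.085). The male-biased fat body gene Cyp4d21 stood higher in monogamous females too, at 3203 ± 925 against 1531 ± 372 (log2 fold change 1.05, limma adjusted p = 0.20). In males to, the takeout gene of the male fat body, stood at 9205 ± 468 under monogamy and 15088 ± 2458 under polygamy (log2 fold change -0.70, limma adjusted p = 0.074). Cyp18a1, which inactivates ecdysone, stood at 779.6 ± 114 against 532.6 ± 47.4 in the same libraries (log2 fold change 0.54, limma adjusted p = 0.075).

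Without the female library of monogamous population 1, camera called further lists in females that it did not call with it: antimicrobial peptide genes lower under monogamy (median -1.05, camera adjusted p = 0.000398), nuclear genes of oxidative phosphorylation lower (-0.19, camera adjusted p = 2.59e-08), and hemocyte (0.40, camera adjusted p = 0.000398) and glial genes (0.05, camera adjusted p = 0.027) higher. None of these held with an estimated correlation in the same libraries, with an adjusted p of 0.374 for hemocyte genes and 0.715 for the other 3 lists. Akh stood at 356 ± 110 in monogamous and 442 ± 204 in polygamous females, close to the 337 ± 87.1 of monogamous males, while polygamous males stood at 1372 ± 230 (n = 3). The difference of the mating effects between the sexes for Akh was -1.80 on the log2 scale (SE 0.52, limma adjusted p = 0.50).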
